A study of Mus musculus with 52 samples.

How the data were processed

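The data were chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from mouse brown adipose tissue (BAT), the tissue that burns lipid to make heat. The series held 52 samples, of which 35 ChIP libraries had a peak list and 17 input libraries had no file used here. Per the labels, samples came from mice at room temperature (RT) or after 4 h of cold. The targets were PPARG, PPARA, PGC1A, CEBPA, CEBPB, ERR1 and the histone mark H3K27ac. PPARA, PGC1A, CEBPA and CEBPB were pulled down through a tag in knock-in mice, all with the same antibody. Per the labels' protocols, H3K27ac samples were fixed with 0.8% formaldehyde for 12 min and the other targets were first treated with 2 mM DSG for 25 min. Groups and replicate numbers were taken from sample titles. The third PGC1A cold library carried a genotype label of the CEBPA knock-in and was grouped by its title. The labels do not say that replicates were separate animals. P-values per locus, and those from permuting libraries, therefore measure the spread between these samples, which may be technical.

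Per the submitters' processing notes, the tools named were Trim Galore 0.6.0, BWA 0.7.17, SAMtools, MACS2 2.2.7.1 and deepTools 3.4.3, with genome build GRCm38.p6. The settings of these tools are not given in the sources used here. The authors deposited 1 narrowPeak list per library, so replicates were not pooled. Each deposited peak has coordinates, a score, a fold enrichment (ratio) at the summit, and a −log10 p-value and −log10 q-value. These values belong to the authors, and were used here to rank or filter peaks within a list. The deposited fold enrichment is also quoted for some named sites, and was not tested. Read depth and fragment numbers are unknown from peak lists, so no depth-based interval or floor was computed, and the number of peaks in a list can move with depth as well as with binding.

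The measured quantity was the peak-covered length of a locus. A locus was a protein-coding gene body with 10 kb on each side on chromosomes 1 to 19 and X, 21631 in all, taken from the supplied gene table of the same build. That table gives no strand and no genome sequence was used, so a site was named by the nearest gene body. In all, 76.3% of loci overlapped another locus, so neighbours can share a peak. Overlapping peaks of a library were merged, covered lengths were scaled to the library total, 500 bp were added and the log2 was taken. Fold changes on that scale understate the change of thinly covered loci. Loci covered in at least as many libraries as the smallest group of the fit were tested with limma 3.58.1 (R 4.3.3; trended empirical Bayes, two-sided, Benjamini-Hochberg threshold 0.05). PPARG and PPARA had fits of their own, and the 14 H3K27ac libraries shared 1 fit. An error after a log2 change is the standard error (SE) of that fit, and covered lengths are mean ± SD.

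The 22 gene lists covered thermogenesis, fatty acid oxidation, de novo lipogenesis, triglyceride synthesis, lipolysis and lipid droplet, lipid uptake, glucose uptake and glycolysis, TCA cycle, oxidative phosphorylation, adipocyte identity, white adipocyte, PPAR target genes, mitochondrial biogenesis, circadian clock, cAMP and immediate early, insulin signalling, heat shock and unfolded protein response, macrophage and lymphocyte, endothelial, skeletal muscle, fibroblast and preadipocyte, and Schwann cell and nerve genes. All names of 21 lists matched the gene table, and 11 of the 12 white adipocyte names did. Lists were tested with camera (limma) at a preset correlation of 0.01, and again with an estimated correlation. At the preset correlation its p-value rests mainly on the spread between genes, and neighbouring loci can share a peak. The genes named were the 6 largest rises and 6 largest falls among called loci whose library values did not overlap between the groups compared. Also named were 18 key genes, and up to 4 members of each list with an adjusted p under 0.05. Genomic position was not a criterion, so neighbouring loci that share peaks can both be named. Sites named were the 5 strongest gained and lost. The text names only some of these genes and sites. That choice was made after their values were seen, and genes whose call held under the alternatives were preferred. Groups, comparisons, gene lists, this rule and the alternatives were fixed before the data were examined, except where a later choice is stated.

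Sites were merged intervals of a target's lists, present in a library that overlapped them by at least 1 bp. A site was gained when all cold lists and no RT list held it, and lost in the opposite case. A consensus site was held by at least 2 libraries of its group, or by the only one. Overlap shares were set beside shares after circular shifts of the sites along each chromosome. Tests on sites were Fisher's exact test, or exact permutation of libraries within a cohort. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

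The code was tested on simulated data. With 100 loci changed by 0.5 and 100 by 1 on the log2 scale, up or down, the PPARG fit over 14095 loci recovered 12 and 74, and the fit for WT H3K27ac over 15163 loci recovered 59 and 97. In each fit the changed loci were drawn from those above the median coverage, so recovery at thinly covered loci was not tested. The fit for cold in Txnip KO over 15163 loci recovered 30 and 92. The PPARA fit over 10212 loci recovered 0 of both, and what its calls rest on was not tested. Covered lengths equalled a count per base in 200 of 200 loci, and the region test over 3 cohorts recovered 0 of 200 gained regions.

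The alternatives tried were no scaling, another pseudocount, no filter, peaks with a −log10 q-value of at least 10 only, lists reduced to equal lengths by rank, a replicate block, only the groups compared in the H3K27ac fit, another overlap rule, and leaving out each library. Gene bodies without flanks, a crossed pairing and a comparison of gained with lost sites were added after the data had been seen. A promoter alternative and a motif search need strand and sequence and were not run. Input libraries were not analysed here.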

Results

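Peak lists from mouse BAT were available for 35 ChIP libraries. PPARG was profiled at RT (n = 3) and after 4 h of cold (n = 3), PPARA in cold (n = 3) and at RT (n = 2), and ERR1 with 1 library per condition. PGC1A (n = 3) and CEBPB (n = 2) were profiled in cold only, and CEBPA (n = 3) at RT only. H3K27ac, a mark of active promoters and enhancers, was profiled in a wild-type (WT) cohort with 3 libraries per condition and in Txnip knockout (KO) and Txnip WT mice with 2 libraries per genotype and condition. PPARG is the master regulator of fat cells, PPARA and PGC1A drive genes of lipid burning, and CEBPA and CEBPB are partners of PPARG. The series title concerns how PPARG and CEBPA respond to acute cold in BAT.

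PPARG lists held 42828 ± 4148 peaks at RT and 36739 ± 3058 in cold (SD, n = 3 each; exact permutation test, two-sided, p = 0.2). They covered 34.8 ± 4.1 Mb at RT and 27.5 ± 3.2 Mb in cold. PPARA lists held 24989 ± 1979 peaks at RT (n = 2) and 8598 ± 2173 in cold (n = 3), a ratio of 0.344, with an exact permutation p of 0.1, the smallest this design allows. The single ERR1 lists held 16020 peaks at RT and 45800 in cold. PGC1A lists held 2717 ± 356 peaks, CEBPA lists 27501 ± 4889 and CEBPB lists 31618 ± 2430. H3K27ac lists of the WT cohort held 57268 ± 2544 peaks at RT and 51945 ± 2949 in cold (exact permutation p = 0.1, the smallest possible). In the libraries labelled Txnip KO the number was 39925 ± 3351 at RT and 54242 ± 835 in cold, and in Txnip WT 41222 ± 2126 and 46375 ± 1659. With 2 libraries each, the exact permutation p cannot fall below 0.333. Median H3K27ac peak widths were 630.5 to 651 bp in the WT cohort and 1152.5 to 1356 bp in the Txnip cohorts, so peak numbers and covered lengths of the WT cohort were not compared with those of the Txnip mice.

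**Figure D1:**
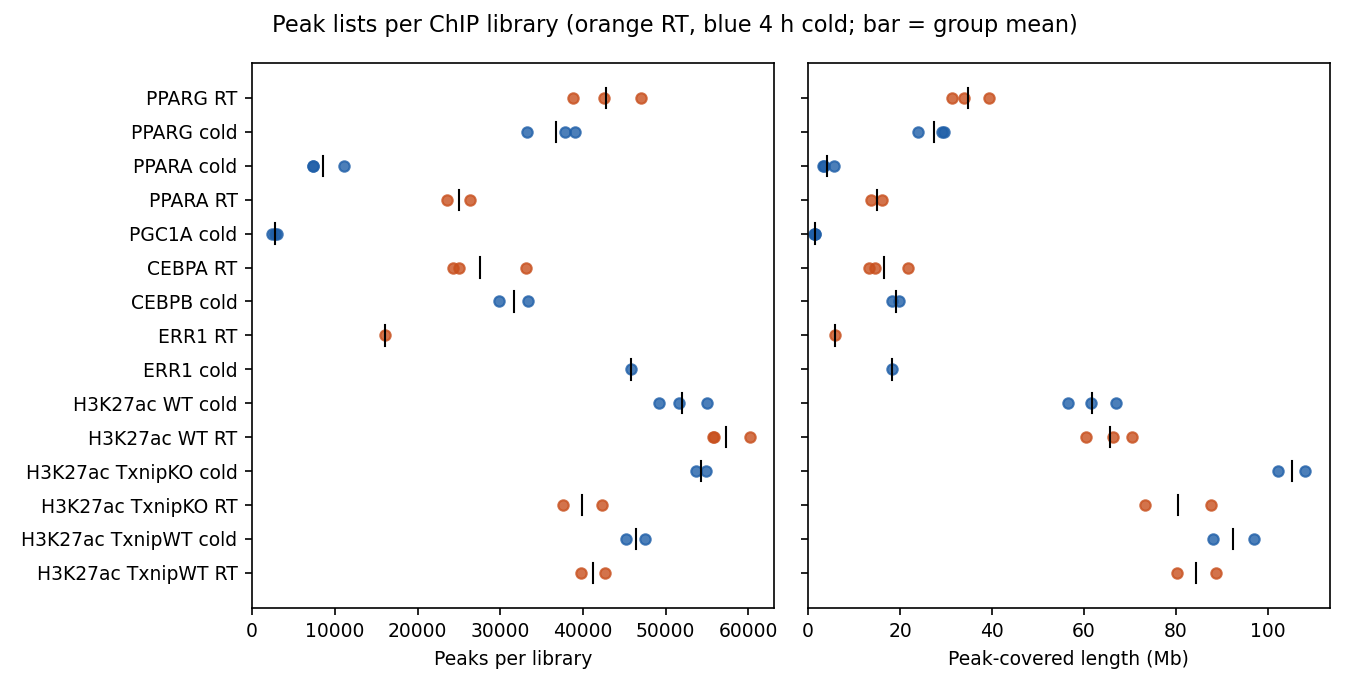
Number of peaks (left) and peak-covered length in Mb (right) of each ChIP library, 1 point per library, with a bar at the group mean. PPARA lists were shorter in cold (8598 peaks on average) than at RT (24989), and the single ERR1 list was longer in cold (45800 against 16020).

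In cold, PPARG coverage rose at loci of blood vessel cells and fell at Cfd. Kdr, the VEGF receptor of endothelial cells (chromosome 5, 75932827 to 75979072, GRCm38.p6), went from 3.67 ± 0.36 kb of PPARG peaks at RT to 9.98 ± 0.21 kb in cold, a log2 change of 1.33 ± 0.10 (adjusted p = 0.00126). Pecam1, an endothelial adhesion molecule, rose by 1.26 ± 0.13, Cdh5, the cadherin of endothelial junctions, by 1.13 ± 0.14, and Sox18, an endothelial transcription factor, by 0.73 ± 0.11, which was lost without scaling (0.42, adjusted p = 0.135) and in the gene body alone (-0.04). Of the 14 endothelial loci tested, 12 were higher and 0 lower, 13 were higher when adjusted over the list alone, and the median change was 0.72 (camera, adjusted p = 9.1e-11). This was the only list of the 22 called for PPARG, and it passed with an estimated correlation too (adjusted p = 0.0396). Markers of other cell types did not pass: fibroblast and preadipocyte genes had 3 higher of 10 (median 0.33, adjusted p = 0.093, but 0.00339 with a median of 0.05 without scaling), macrophage and lymphocyte genes 1 lower of 7 (adjusted p = 0.812), skeletal muscle genes 1 higher and 1 lower of 9 (adjusted p = 0.911), and Schwann cell and nerve genes 1 higher and 1 lower of 7 (adjusted p = 0.719).

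Cfd, which encodes the adipocyte-secreted protease adipsin (chromosome 10, 79890853 to 79892655), fell from 4.81 ± 0.64 kb to 0.393 ± 0.34 kb, a log2 change of -2.65 ± 0.30 (adjusted p = 0.0036). Its neighbour Elane, the gene of neutrophil elastase, shares part of the same peaks and changed by -2.28 ± 0.14. Sh3gl3 fell by 2.19 on the log2 scale, and no PPARG peak was listed at Chst9 in any cold library, against 2.12 ± 0.66 kb at RT. Scd1, the desaturase of fat synthesis, changed by -0.63 ± 0.11, Cebpa, the gene of a PPARG partner, by -0.53 ± 0.10, and Acly, which makes acetyl-CoA for lipogenesis, by -0.44 ± 0.12 (adjusted p = 0.0116, 0.0158 and 0.0484). The Cebpa call ended without RT replicate 1 (adjusted p = 0.0611) and in the gene body alone (0.268). The Acly call ended in the gene body alone (0.176), without RT replicate 1, 2 or 3 (0.097, 0.173 and 0.112) and without cold replicate 1, 2 or 3 (0.107, 0.0777 and 0.112). Among the largest rises were those at Kcnc4, a potassium channel (2.18 ± 0.33), and at the adjoining genes Ripk3, a kinase of necroptosis (2.16 ± 0.27), and Adcy4, an adenylate cyclase (1.92 ± 0.30, lost in the gene body alone with an adjusted p of 0.354). Wdr95 had 1.90 ± 0.26 kb in cold and no peak in any RT library. Ucp1, the uncoupling protein that makes heat, gave 0.13 ± 0.09 (adjusted p = 0.417), Ppargc1a, the gene of PGC1A, 0.31 ± 0.11 (0.103, but 0.42 and 0.0492 with stricter peaks), and Fasn, the fatty acid synthase, -0.29 ± 0.23 (0.485).

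De novo lipogenesis genes split into 1 higher and 5 lower of 20 for PPARG (median -0.08, adjusted p = 0.224), and thermogenesis genes into 2 higher and 3 lower of 25 (adjusted p = 0.786). In all, 1434 of 14105 loci changed (limma, adjusted p under 0.05), 711 higher and 723 lower, with a median size of 0.79 on the log2 scale among the called loci. The median change over all loci was 0.03 with scaling and -0.22 without. Without scaling the split was 155 higher and 1346 lower, and the endothelial median was 0.40. Unscaled, the lists of de novo lipogenesis (median -0.36, adjusted p = 0.0272), lipolysis and lipid droplet (-0.39, 0.00546) and adipocyte identity genes (-0.32, 0.0469) were called as well, lower relative to other loci. The count of called loci depended on single libraries: without RT replicate 1, 2 or 3 it was 529, 624 or 830, and without cold replicate 1, 2 or 3 it was 740, 767 or 866.

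**Figure D2:**
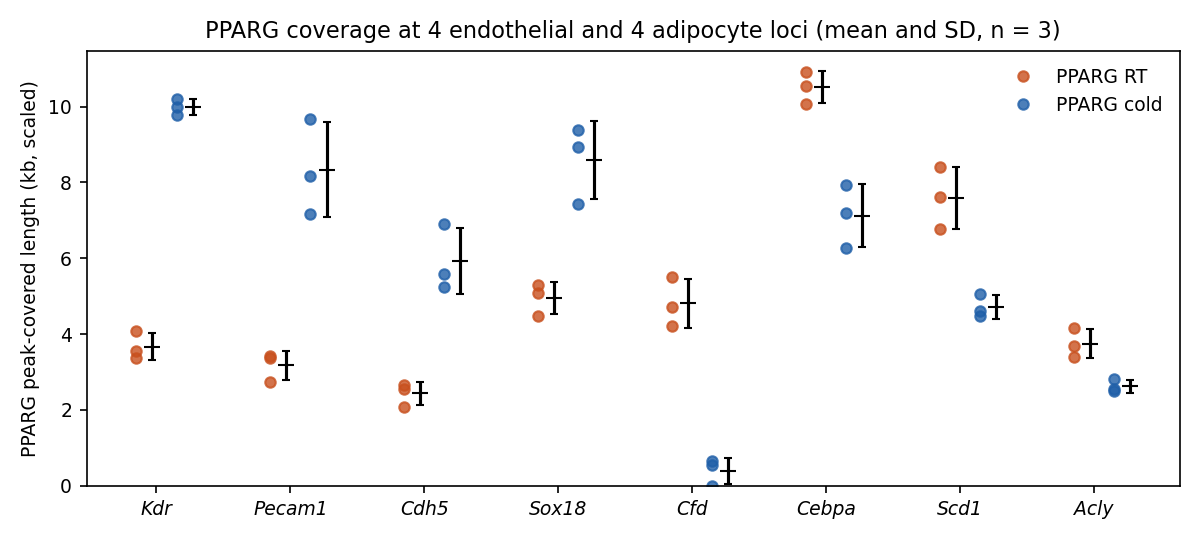
PPARG peak-covered length (kb, scaled to the library total) at 4 endothelial and 4 adipocyte loci, with points for libraries and a bar for mean ± SD (n = 3 per condition). Kdr rose from 3.67 to 9.98 kb and Cfd fell from 4.81 to 0.393 kb.

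Single PPARG sites were compared next. Of 59517 merged sites, 22582 (37.9%) were in all 6 libraries, 1044 were gained in cold and 3137 lost, or 1850 and 2364 with lists of equal length. With lists equally likely to hold a site, chance puts 10% of sites found in exactly 3 of 6 libraries into these sets. The strongest gained site lay within Scp2, a sterol carrier gene (chromosome 4, 108138930 to 108140094), with a deposited fold enrichment of 23.4 to 25.2 in the cold libraries. Others lay 7.16 kb from Pecam1 (chromosome 11, 106722438 to 106723620), within Fkbp5, a glucocorticoid-responsive chaperone gene (chromosome 17, 28463452 to 28464505), and 21.8 kb from Socs2, a brake on growth hormone signalling (chromosome 10, 95361143 to 95362081). The strongest lost site covered part of Cfd (chromosome 10, 79889194 to 79891589), with a fold enrichment of 54.5 to 57.5 at RT. The number of gained and lost sites together was 6739 without RT replicate 3, against 4181.

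**Figure D3:**
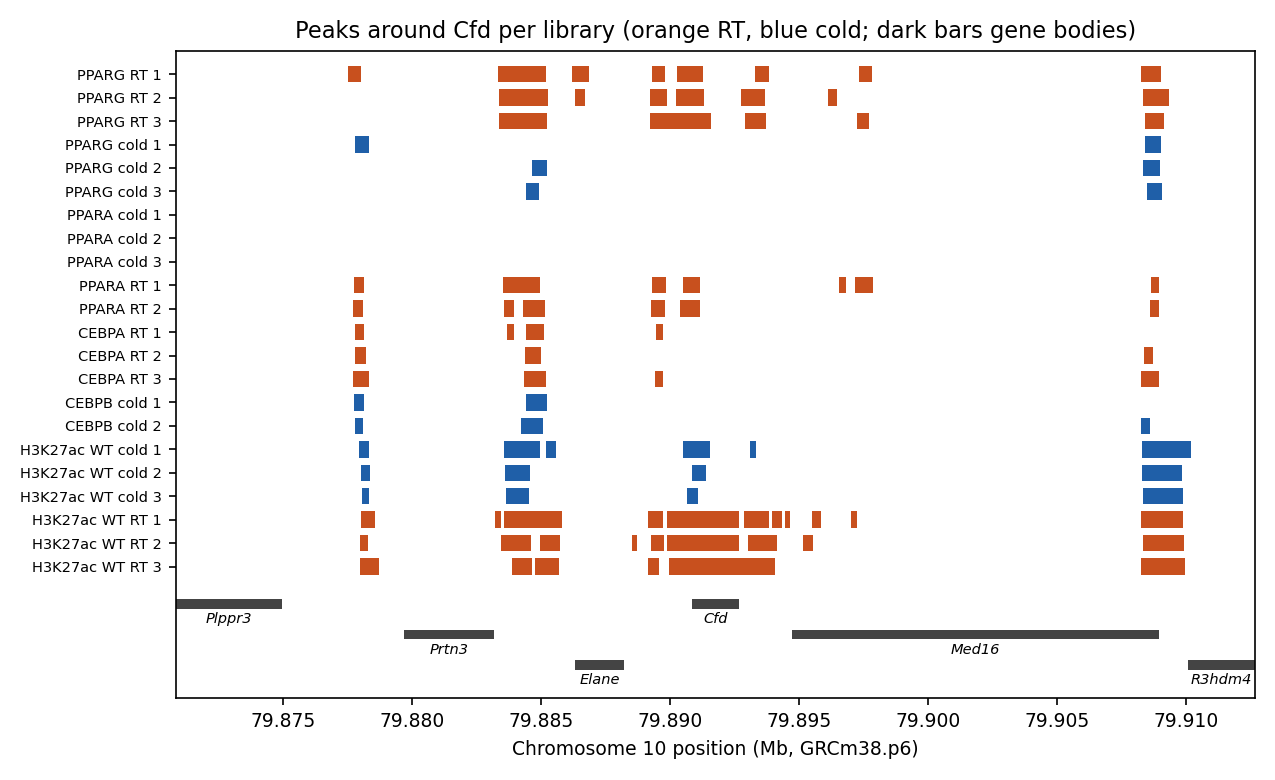
Peaks of each library around Cfd on chromosome 10 (position in Mb, GRCm38.p6), with RT libraries in orange, cold libraries in blue and gene bodies as dark bars. PPARG covered 4.81 kb of the locus at RT and 0.393 kb in cold, and no PPARA peak was listed in cold.

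PPARA lists were shorter in cold, and coverage relative to the library total was higher at some genes of lipid burning, a rise that depended on scaling and list length. Ucp1 (chromosome 8, 83290348 to 83298456) went from 2.30 ± 0.087 kb at RT (n = 2) to 6.89 ± 1.6 kb in cold (n = 3), a log2 change of 1.38 ± 0.20 (adjusted p = 0.00615), and Ppargc1a rose by 1.14 ± 0.19 (adjusted p = 0.00913). Etfdh, which passes on electrons from fatty acid oxidation, rose by 1.06 ± 0.21 (adjusted p = 0.0165). Without scaling these turned negative (Ucp1 -0.28, Ppargc1a -0.64, Etfdh -0.19), and Ppargc1a was then called lower (adjusted p = 0.0304), where the median change over all loci was -1.09, against -0.44 with scaling, and Ucp1 was negative in the gene body alone too (-0.39). Lists of equal length ended the calls of Ucp1 (0.45, adjusted p = 0.346) and Etfdh (0.27, 0.346), and the calls of Ppargc1a and Etfdh ended without RT replicate 1 (0.541 and 0.828) or 2 (0.342 and 0.578). Slc2a1, the glucose transporter GLUT1, had a rise among the largest (2.24 ± 0.34; not called without scaling, adjusted p = 0.0977, or with stricter peaks, 0.247), and Prkcb, a protein kinase C gene, rose by 2.06 ± 0.22 (0.0642 without scaling). No PPARA peak was listed in any cold library at Zhx2, a repressor gene, at Cfd, Elane, Cebpd, or Cox7a1, a subunit of complex IV, which at RT had 2.63, 1.74, 1.95, 0.703 and 0.606 kb.

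Of the 22 lists, 9 were called for PPARA, all up relative to other loci, and all 9 calls depended on the setting. Without scaling each median was negative and no list was called (adjusted p = 0.43 to 0.937), and with an estimated correlation each call was lost. With lists of equal length each call was lost too (adjusted p = 0.496 to 0.906), with medians of 0.00153 for fatty acid oxidation, 0.03 for PPAR targets, 0.03 for triglyceride synthesis, 0.08 for glucose uptake and glycolysis and 0.15 for circadian clock genes, and of -0.000843 for lipolysis, -0.05 for thermogenesis, -0.11 for adipocyte identity and -0.45 for de novo lipogenesis. Fatty acid oxidation genes gave 8 higher and 0 lower of 24, 8 higher adjusted over the list alone, median 0.61 (adjusted p = 1.0e-09; adjusted p = 0.101 with an estimated correlation). PPAR target genes gave 3 higher of 21 (1 over the list alone), median 0.53 (4.6e-07; 0.101 estimated). Glucose uptake and glycolysis genes gave 6 higher and 1 lower of 23 (the same numbers over the list alone), median 0.38, and lipolysis and lipid droplet genes 4 higher of 16 (4 over the list alone), median 0.36. Triglyceride synthesis genes gave 2 higher of 14 (1 over the list alone), median 0.61. Circadian clock genes gave 3 higher of 19 (1 over the list alone), median 0.31, led by the clock activator gene Arntl (1.20 ± 0.11). Adipocyte identity genes gave 5 higher and 2 lower of 20 (6 and 3 over the list alone), median 0.27, the fallen ones being Cfd and Cebpd. Thermogenesis genes gave 5 higher and 3 lower of 23 (5 and 3 over the list alone), median 0.10. De novo lipogenesis genes gave 1 higher of 17 (1 over the list alone), the elongase gene Elovl6 (1.29 ± 0.16), with a median of 0.06 but a mean of -0.06, so the mean ran against the test. For the 7 lists from glucose uptake to lipogenesis the adjusted p was 0.000128, 0.000101, 0.000664, 0.000383, 0.000898, 0.0134 and 0.0298, and with an estimated correlation 0.122, 0.115, 0.115, 0.115, 0.115, 0.146 and 0.18. Without scaling Arntl and Elovl6 turned negative (-0.45 and -0.42), equal list lengths ended both calls (adjusted p = 0.196 and 0.0938), as did leaving out RT replicate 1 (0.0647 and 0.109), and Arntl was lost without RT replicate 2 (0.127) and with stricter peaks (0.0546).

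Across the genome 3614 of 10231 loci changed for PPARA (limma), 431 higher and 3183 lower, and without scaling 8 were higher and 6851 lower. The RT group had only 2 libraries. Without RT replicate 1 or 2, loci covered only in the other RT library fell below the filter. The median change over all loci was then -0.09 or -0.08, against -0.44 with all libraries. Most calls ended, and those left lay mostly higher, whereas most calls with all libraries lay lower. With lists reduced to equal length 379 loci were called, 121 higher and 258 lower, and with stricter peaks 1990, 202 higher and 1788 lower. At single sites, 83 of 33531 were gained and 8081 lost, or 500 and 1018 with lists of equal length. If all lists were equally likely to hold a site, chance would put 10% of sites in exactly 3 of 5 libraries into the gained set. The same share of sites in exactly 2 would fall into the lost set. PPARA lists were shorter in cold (8598 peaks against 24989), which alone favours the lost set, so this 10% is no chance level for these counts. The strongest gained ones lay 23.3 and 22.1 kb from Socs2 and within Scp2. The strongest lost one lay 16.1 kb from Cebpa (chromosome 7, 35138045 to 35139071; deposited fold 46.6 to 49.4 at RT), and another within Cfd (chromosome 10, 79890376 to 79891167). Gained and lost sites together numbered 12995 without RT replicate 1 and 15485 without RT replicate 2, against 8164.

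Across loci, the PPARG change in cold ran with the H3K27ac change of the WT cohort (Pearson r 0.45, Spearman rho 0.43 over 13620 loci, which are not independent). In both, 258 loci were higher (40.8 expected of independent lists) and 232 lower (47.4), and 4 were called in opposite directions. PPARG and PPARA changes gave r = 0.23, with 70 loci higher in both (19.1 expected), 210 lower (177 expected) and 88 called in opposite directions. Gained PPARG sites overlapped a gained H3K27ac region at 5.46% of 1044 sites, against 0.58% of the 22582 stable sites (odds ratio 9.90, Fisher's exact test, two-sided, adjusted p = 7.6e-32). Lost PPARG sites overlapped a lost H3K27ac region at 4.62%, against 1.91% (odds ratio 2.49, adjusted p = 7.5e-18). Any H3K27ac region lay at 90.0% of stable, 68.4% of gained and 44.2% of lost sites. The sets thus differed in how many sites could gain or lose a region, which enters these odds ratios. Set directly side by side, gained and lost PPARG sites overlapped a gained region at 5.46% and 0.0638%, and a lost region at 0% and 4.62%. Sites of the same libraries are not independent replicates, so the Fisher p-values of this paragraph measure spread over sites and not between libraries. CEBPA at RT occupied 26.7% of the lost, 13.7% of the gained and 53.4% of the stable PPARG sites, and CEBPB in cold occupied 14.8%, 27.7% and 47.7%. The direct comparison of gained with lost sites, added after the data were seen, gave an odds ratio of 0.435 for CEBPA (adjusted p = 5.0e-19) and 2.21 for CEBPB (2.1e-19). CEBPA was profiled only at RT, where lost sites were bound, and CEBPB only in cold, where gained sites were bound, so factor and temperature cannot be separated here.

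H3K27ac in the WT cohort was compared between cold and RT. Mfsd2a, a lysophospholipid transporter gene (chromosome 4, 122946850 to 122961194), rose from 0.300 ± 0.33 to 4.16 ± 0.17 kb (log2 change 2.62 ± 0.46, adjusted p = 0.00439; n = 3 per condition). Dio2, the enzyme that activates thyroid hormone in BAT (chromosome 12, 90724552 to 90739038), rose from 3.10 ± 0.53 to 9.48 ± 0.35 kb (1.48 ± 0.15, adjusted p = 0.000401), and Ppargc1a rose by 0.70 ± 0.17 (adjusted p = 0.0231). Genes of fat synthesis fell: Scd1 by 0.96 ± 0.18, Srebf1, the lipogenic transcription factor, by 1.12 ± 0.17, Pnpla3 by 1.33 ± 0.24 and Fasn by 0.89 ± 0.22 on the log2 scale. Apln, the gene of the vessel hormone apelin, changed by -2.36 ± 0.28, Wscd2 by -2.47 ± 0.31 and the neurotrophin receptor gene Ntrk3 by -2.28 ± 0.23. Ucp1 gave -0.10 ± 0.14 (adjusted p = 0.715). The Ppargc1a call ended without scaling (adjusted p = 0.126) and without cold replicate 2 (0.0571) or 3 (0.0808), and the Fasn call with stricter peaks (0.0599) and without cold replicate 2 (0.0807), cold replicate 3 (0.0914), RT replicate 1 (0.0899) or RT replicate 3 (0.0604).

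In the WT cohort 5 lists were called, and each call was lost with an estimated correlation. cAMP and immediate early genes, the first targets of adrenergic signalling, gave 9 higher and 0 lower of 24 (14 adjusted over the list alone), median 0.23, adjusted p = 5.1e-07, and adjusted p = 0.239 with an estimated correlation. Among them Sik1 rose by 0.99 ± 0.15, Nr4a1 by 0.93 ± 0.12 and Maff by 0.87 ± 0.10. Endothelial genes gave 7 higher and 0 lower of 15 (11 over the list alone), median 0.28, adjusted p = 2.4e-06 (0.583 estimated), led by Cdh5 (0.77 ± 0.08) and Kdr (0.57 ± 0.09). De novo lipogenesis genes gave 6 lower and 0 higher of 20 (8 over the list alone), median -0.40, adjusted p = 0.000163 (0.583 estimated). White adipocyte genes gave 4 lower and 1 higher of 9 (5 and 1 over the list alone), median -0.51, adjusted p = 0.00882 (0.239 estimated, and 0.107 with lists of equal length): Lep, the gene of leptin, had no peak in any cold library against 1.59 ± 0.98 kb at RT, Nnat changed by -0.88 ± 0.15, and Agt, the gene of angiotensinogen, rose by 1.05 ± 0.19. Fatty acid oxidation genes gave 4 lower and 1 higher of 24 (5 and 1 over the list alone), median -0.18, adjusted p = 0.0233 (0.953 estimated), with the isomerase gene Eci1 at -0.60 ± 0.12. Stricter peaks ended the calls of Lep (adjusted p = 0.404) and Nnat (0.101), and the gene body alone ended those of Nnat (0.0958) and Eci1 (0.0856).

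The other 17 lists did not pass in the WT cohort, although adipocyte identity genes (adjusted p = 0.271) passed without scaling, lower relative to other loci (0.0458). Adjusted p was 0.287 for thermogenesis, 0.923 for mitochondrial biogenesis, 0.46 for heat shock and unfolded protein response, 0.864 for macrophage and lymphocyte, 0.545 for skeletal muscle, 0.871 for fibroblast and preadipocyte and 0.867 for Schwann cell and nerve genes. In all, 1811 of 15163 loci changed (limma), 818 higher and 993 lower, and without scaling 184 higher and 829 lower. The count was 867 without cold replicate 2, 1022 without cold replicate 3, 851 without RT replicate 1 and 1028 without RT replicate 2. Of 67181 merged regions, 769 were gained and 1633 lost (1003 and 1201 with lists of equal length). Lists equally likely to hold a region would put 10% of regions found in exactly 3 of 6 libraries there by chance. The strongest gained region lay in Mfsd2a (chromosome 4, 122958283 to 122961351) and lost ones lay 3.98 kb from Car3, a carbonic anhydrase gene, and 37.6 kb from Scd1. Gained and lost regions together numbered 4221 without cold replicate 1, 3993 without RT replicate 2 and 4625 without RT replicate 3, against 2402.

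**Figure D4:**
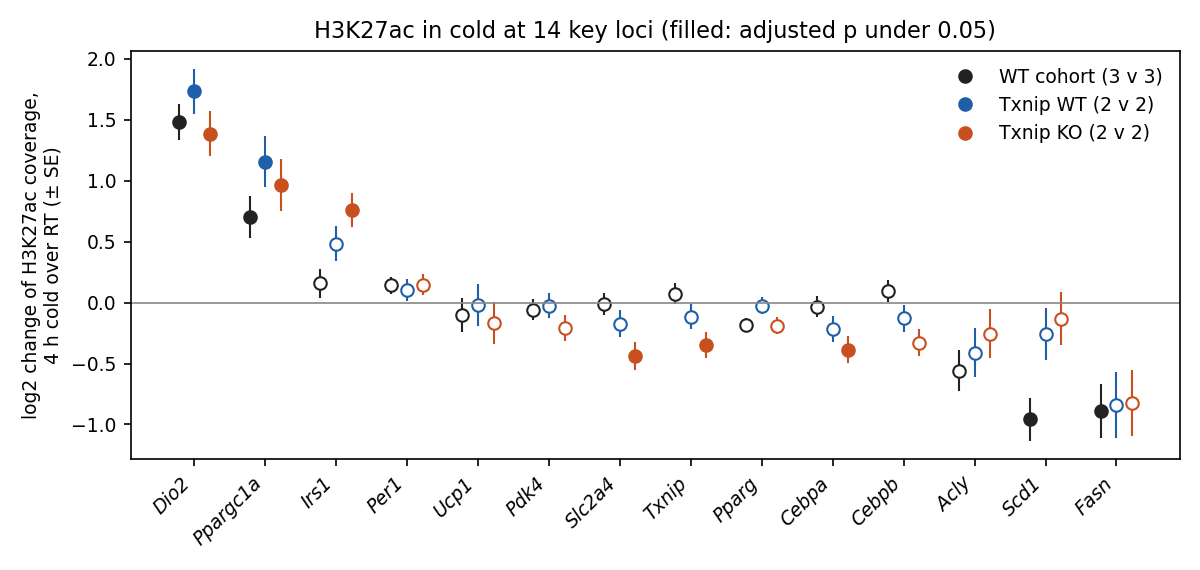
Log2 change of H3K27ac coverage (cold over RT, ± SE) at 14 key loci in the WT cohort (3 against 3 libraries), Txnip WT and Txnip KO (2 against 2 each), with filled points for an adjusted p under 0.05. Dio2 rose in all 3 (1.48, 1.73 and 1.39), and Ucp1 stayed within -0.17 to -0.02 with no call.

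Txnip encodes an arrestin that restrains glucose uptake. At Txnip itself (chromosome 3, 96557957 to 96561857), 1 H3K27ac peak covered 100% of the 3.901 kb gene in all 14 libraries, 31.4 to 33.6 kb long in the libraries labelled Txnip KO and 30.4 to 31.6 kb in those labelled Txnip WT. A deletion inside the gene that leaves the mark in place would look the same, so this does not check the genotype labels.

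In Txnip WT mice cold raised H3K27ac at Dio2 by 1.73 ± 0.18 (adjusted p = 0.000835) and at Ppargc1a by 1.16 ± 0.21 (adjusted p = 0.0093; n = 2 per condition). St8sia1, a ganglioside synthase gene, had 2.99 ± 1.0 kb in cold and no peak at RT, whereas Chst9 had 2.97 kb at RT and none in cold. Oxidative phosphorylation genes gave 5 higher and 0 lower of 28 (7 adjusted over the list alone), median 0.21, adjusted p = 0.00202. Insulin signalling genes gave 3 higher of 22 (7 over the list alone), median 0.26, adjusted p = 0.00202, although Irs1, the docking protein of the insulin receptor, did not pass (0.48 ± 0.14, adjusted p = 0.069, or 0.0253 without cold replicate 1). With an estimated correlation these gave adjusted p = 0.75 and adjusted p = 0.314. Endothelial genes gave 1 higher of 15, median -0.08 (adjusted p = 0.585), and the other 19 lists did not pass either, although cAMP and immediate early genes (adjusted p = 0.0881) passed without scaling (0.0127) and with lists of equal length (0.0322). In all 1050 loci changed, 688 higher and 362 lower, and 849 and 172 without scaling, where the median shift was 0.12. Without cold replicate 1 or 2 the count was 393 or 528, and without RT replicate 1 or 2 it was 316 or 292. The Ppargc1a call ended without cold replicate 1, RT replicate 1 or RT replicate 2 (adjusted p = 0.0683, 0.064 and 0.0562).

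In the libraries labelled Txnip KO cold raised H3K27ac at Dio2 by 1.39 ± 0.18 (adjusted p = 0.00182), at Ogdh, a dehydrogenase of the TCA cycle, from 5.63 ± 0.22 to 16.8 ± 0.44 kb (1.49 ± 0.13, adjusted p = 0.000205), and at Pik3ca, the PI3-kinase catalytic subunit gene, by 1.42 ± 0.19 (n = 2 per condition). Among the largest rises was that at P2ry14, a receptor gene with 5.36 ± 1.1 kb in cold and no peak at RT. Lrrc55 changed by -2.34 ± 0.23, and Hmcn1 had 2.70 kb at RT and no peak in cold. TCA cycle genes gave 7 higher and 1 lower of 17 (8 and 2 adjusted over the list alone), median 0.26, adjusted p = 0.0174 and adjusted p = 0.851 with an estimated correlation, with Sdhc at 1.35 ± 0.23. Insulin signalling genes gave 7 higher and 1 lower of 22 (the same over the list alone), median 0.24, adjusted p = 0.00539 (0.554 estimated). Macrophage and lymphocyte genes gave 2 higher of 14 (2 over the list alone), median 0.42, adjusted p = 0.00774 (0.851 estimated), lost without scaling (adjusted p = 0.264, median 0.78), where Itgam, a macrophage integrin gene, rose by 1.87 ± 0.38 but lost its call without cold replicate 1 (adjusted p = 0.0839) or RT replicate 1 (0.093).

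The falling lists of the Txnip KO libraries held adipocyte and vessel genes, and without scaling, where the median shift was 0.30, each median turned positive and each call ended (adjusted p = 0.152, 0.327, 0.411 and 0.498 in the order given). Endothelial genes gave 5 lower of 15 (7 over the list alone), median -0.30 scaled and 0.09 unscaled, adjusted p = 0.00448. Lipid uptake genes gave 3 lower of 17 (9 over the list alone), median -0.27 and 0.09 unscaled, adjusted p = 0.00448. Adipocyte identity genes gave 5 lower of 20 (8 over the list alone), median -0.22 and 0.16 unscaled, adjusted p = 0.00539, with Stat5a at -0.69 ± 0.11 (-0.32 and adjusted p = 0.0658 unscaled). Lipolysis and lipid droplet genes gave 5 lower of 16 (7 lower and 1 higher over the list alone), median -0.24 and 0.14 unscaled, adjusted p = 0.0274 (0.0739 with lists of equal length). With an estimated correlation these gave adjusted p = 0.851, 0.851, 0.851 and 0.939. In all 2156 loci changed, 1172 higher and 984 lower, and 4294 and 130 without scaling. A limma fit of these 4 libraries alone called 0 loci (3633 at an unadjusted p under 0.05), so every call of this comparison rests on the spread shared with the other cohorts. The count was 725 without cold replicate 1 and 524 without RT replicate 1.

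The genotypes were compared within each temperature. At RT, Mrps18a, a mitochondrial ribosome gene, had 4.71 ± 0.61 kb of H3K27ac in the libraries labelled Txnip KO and 1.11 ± 0.44 kb in Txnip WT (log2 difference 1.72 ± 0.21, adjusted p = 0.0147). Vipr2, a VIP receptor gene, had no peak in KO against 2.25 ± 0.14 kb in WT (adjusted p = 0.00495). The Mrps18a call ended with stricter peaks (0.228), without KO RT replicate 1 (0.107) and without WT RT replicate 2 (0.107), and the Vipr2 call without WT RT replicate 1 (0.074). In all 12 loci differed at RT, 2 higher and 10 lower in KO, with 3 called without Txnip WT RT replicate 1 and 5 without its replicate 2. Macrophage and lymphocyte genes (median 0.32, adjusted p = 0.0046), de novo lipogenesis genes (0.22, 0.00429), oxidative phosphorylation genes (0.13, 0.00173) and cAMP and immediate early genes (0.10, 0.00429) lay higher in KO, with 0 members called over all loci and 0, 0, 2 and 2 adjusted over the list alone (unadjusted, 1179 loci passed in limma). Each of the 4 gave adjusted p = 0.779 with an estimated correlation.

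In cold, Ahcyl2 had 14.5 ± 1.7 kb in the libraries labelled Txnip KO and 3.31 ± 1.8 kb in Txnip WT (2.06 ± 0.30, adjusted p = 0.025), and Tlr13, an innate immune receptor gene, had 2.34 ± 1.4 kb in KO and no peak in WT. Zfp697 was lower in KO (-1.81 ± 0.15, adjusted p = 0.00133), as was Unc5b, a netrin receptor gene of vessels (-1.13 ± 0.17). Without WT cold replicate 1 the calls of Ahcyl2, Tlr13 and Unc5b ended (0.118, 0.0814 and 0.166), without KO cold replicate 1 those of Ahcyl2 and Unc5b (0.0888 and 0.104), with stricter peaks that of Ahcyl2 (0.103) and without scaling that of Unc5b (0.0526). In all 67 loci differed, 50 higher and 17 lower in KO, and 208 and 12 without scaling, where the median shift was 0.14. The count was 1 without KO cold replicate 1, 504 without KO cold replicate 2 and 3 without WT cold replicate 1. Macrophage and lymphocyte genes were higher (median 0.40, 0 of 14 called, 3 over the list alone, adjusted p = 4.3e-05) and endothelial genes lower in KO (median -0.26, 0 of 15 called, 3 over the list alone, adjusted p = 4.3e-05). De novo lipogenesis (median 0.18, adjusted p = 0.0223, 0 of 20 called in either way) and TCA cycle genes (0.10, 0.0446, 0 of 17 called, 2 over the list alone; adjusted p = 0.0939 with lists of equal length) lay higher. All 4 gave adjusted p = 0.874 with an estimated correlation. Limma fits of the compared libraries alone called 0 loci at RT and 0 in cold (1167 and 1757 at an unadjusted p under 0.05). In the shared fit 2311 passed unadjusted in cold. Ucp1 differed by -0.01 ± 0.17 at RT and -0.16 ± 0.17 in cold, with no call.

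Whether cold acted differently in the genotypes was tested as an interaction. It called 5 loci, Grm7, Nat8f2, Septin12, Vipr2 and Septin3 (limma, adjusted p = 0.0352 each), 4 higher and 1 lower, and 15 and 1 without scaling, where the median shift was 0.17. A limma fit of the 8 Txnip libraries alone called 0 (1239 unadjusted, against 1411). Lists of equal length ended the calls of Grm7, Nat8f2, Septin12 and Vipr2 (limma, adjusted p = 0.09, 0.245, 0.412 and 0.17). With stricter peaks 0 of the 5 were called. Leaving out KO cold 1, KO RT 2, WT cold 2 or WT RT 2 gave 0, WT cold 1 or WT RT 1 gave 1, KO RT 1 gave 2, and KO cold 2 gave 131, and each of the 5 named loci lost its call when any library other than KO cold 2 was left out. The list medians of cAMP and immediate early genes (-0.15, 0 of 24 called, 1 lower over the list alone, adjusted p = 0.0341, or 0.12 with lists of equal length) and endothelial genes (-0.25, 0 of 15 called in either way, adjusted p = 0.00327) lay lower in KO, turned positive without scaling (0.10 and 0.01, adjusted p = 0.781 and 0.174), and gave adjusted p = 0.845 with an estimated correlation.

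The cold response of H3K27ac was compared between the WT, Txnip WT and Txnip KO libraries, which share no library but were fitted together with 1 spread per locus. In all 3, 100 loci rose and 85 fell, against 2.87 and 1.54 for independent lists, which is not the number without a cold response given the shared fit. In a limma fit of its own groups Txnip KO called 0 loci (3633 unadjusted), so no locus is called in all 3 there, and the KO calls named next ended too (adjusted p from 0.0704 to 0.0826), as did Zdhhc19 in Txnip WT (0.0650). Among the risen, Fkbp5, named here after its values were seen, changed by 1.45, 2.17 and 1.63 in WT, Txnip WT and Txnip KO, Dio2 by 1.48, 1.73 and 1.39, and Acot5, an acyl-CoA thioesterase gene, by 1.28, 1.87 and 1.85. Among the fallen, Zdhhc19, a palmitoyltransferase gene, changed by -1.27, -1.12 and -1.44, and Tango6, a gene of protein transport, by -0.92, -1.39 and -1.53. The correlation of changes across loci, which are not independent, was 0.43 for WT with Txnip WT, 0.12 for WT with Txnip KO and 0.58 for Txnip WT with Txnip KO, and 10, 87 and 4 loci were called in opposite directions. Over 67543 merged regions, 68 were present in all 7 cold and no RT library and 25 in the opposite way. Chance alone gives at most 130 such regions, a bound too loose to test the 93 found, so these counts show no shared change by themselves. A gained region in Ppargc1a (chromosome 5, 51565162 to 51569111) is one of them. Exact permutation within cohorts called 0 of 46952 regions (1125 at an unadjusted p under 0.05), and its smallest possible p of 0.00278 would need 2609 such regions to pass adjustment.

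PGC1A sites in cold were set beside those of the other targets. Of the peaks of each PGC1A library, 98.7% ± 0.28 (SD, n = 3) overlapped an ERR1 site in cold, the orphan receptor through which PGC1A acts on mitochondrial genes, 92.8% ± 0.23 an H3K27ac region, 90.5% ± 0.75 a PPARG site and 59.0% ± 1.8 a PPARA site. CEBPA sites of RT were shared by 69.0% ± 0.51 and CEBPB sites of cold by 66.3% ± 0.90. After circular shifts the shares were 1.70%, 3.73%, 2.14%, 0.349%, 1.39% and 1.32% in that order. With all partner lists reduced to the length of the shortest, that of PPARA, the share was 86.8% for ERR1, 59.0% for PPARA, 46.8% for H3K27ac, 43.0% for PPARG, 31.9% for CEBPA and 29.5% for CEBPB, so the order of partners depended in part on list length. Of 2485 consensus sites, 1596 (64.2%) lay on sites of PPARG, ERR1 and CEBPB together, and 8 (0.322%) on none of the 5 factors. Acacb, which makes malonyl-CoA, had 7 PGC1A sites nearest to it, and Ppara 5. The third library, whose genotype label named the CEBPA knock-in, shared 68.4% and 63.0% of its 3057 peaks with the other 2, and held 76.3% and 82.3% of theirs.

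**Figure D5:**
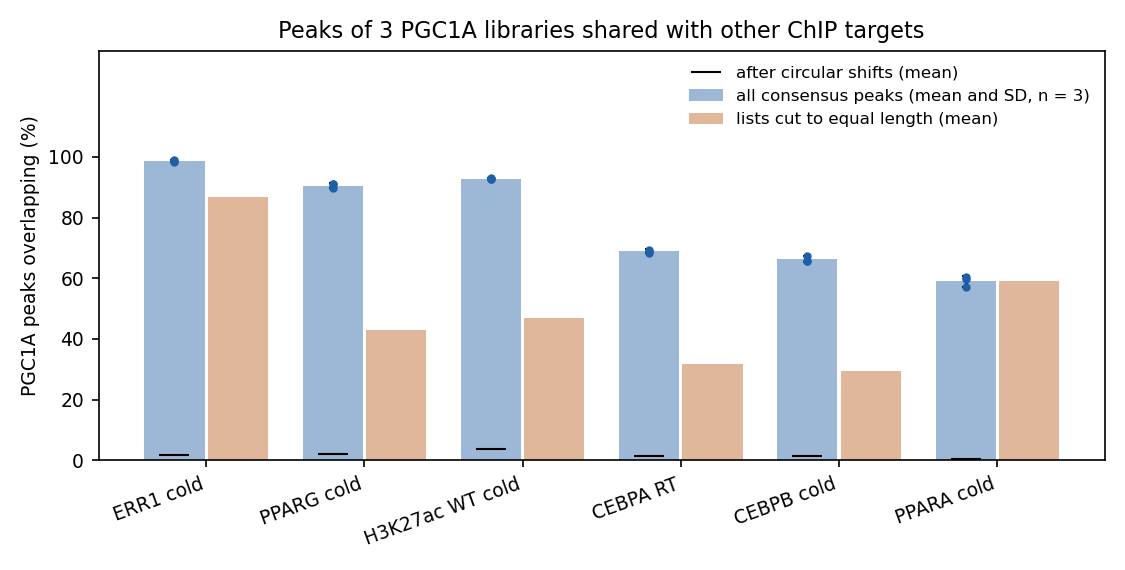
Percent of PGC1A peaks that overlap sites of other ChIP targets, for all consensus peaks (blue bars, mean ± SD, n = 3, points for libraries), for partner lists of equal length (orange bars) and after circular shifts (black lines). ERR1 was shared by 98.7%, and by 86.8% at equal length.

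Among other pairs, 98.4% of PPARA consensus sites in cold lay on a PPARG site, and 77.1% of CEBPA sites at RT on a CEBPB site in cold. CEBPA shared 70.8% of its sites with PPARG at RT. ERR1 shared 53.3% of its cold sites with PPARG. ERR1 was sampled once per condition, so its difference has no replicate check. The RT list was nearly contained in the cold list: 94.9% of RT peaks were found in cold (Wilson 95% interval 94.5 to 95.2), while 32.4% of cold peaks were found at RT. Against random lists of matched coverage, the cold-minus-RT medians of the 22 lists ran from percentile 0.05 for oxidative phosphorylation to 99.1 for circadian clock genes. With equal list lengths the extremes were other lists, and such percentiles measure spread between genes, so no ERR1 list change is claimed.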

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

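The tests of the endothelial and immune patterns, of the PPARA sites missing where PPARG was kept, and the counts over other splits were chosen after the results were seen, and the test of PPARA sites missing together with PPARG was chosen before, then split after the result was seen by whether PPARG was lost or kept. Of the cold changes in H3K27ac, 5 loci differed between the genotypes by the interaction test (limma, adjusted p = 0.0352 each). Given as KO minus WT on the log2 scale, these were 3.41 at Grm7, a glutamate receptor gene, 3.30 at Nat8f2, 2.88 at Septin12, 2.86 at Vipr2 and -2.10 at Septin3. Covered lengths in KO cold, KO RT, WT cold and WT RT were 2.23, 1.34, 0 and 3.17 kb at Grm7 and 0.183, 0, 0 and 2.25 kb at Vipr2. With groups at 0 the size depends on the pseudocount: at 100 bp it was 5.68 at Grm7 (adjusted p = 0.196) and 5.66 at Vipr2 (0.0619), neither called. In the gene body alone Septin12 gave 0.42 (adjusted p = 0.581). Each of the 5 calls ended when any library other than KO cold replicate 2 was left out. The list medians of cAMP and immediate early genes (-0.15) and of endothelial genes (-0.25) were lower in KO, calls that were lost with an estimated correlation (adjusted p = 0.845 for both). Without scaling they were 0.10 and 0.01, where the median over all loci moved from -0.06 to 0.17. Outside the chromosomes compared, each of the 14 H3K27ac libraries had peaks on chromosome Y, 5 at the fewest and 9 at the most. The labels used give no sex, and these peaks were not analysed further.

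PPARG coverage was higher in cold at endothelial loci such as Kdr and Pecam1. A lower share of adipocyte nuclei would raise PPARG coverage only at markers of cell types that carry PPARG. Which types do was not measured, so a contrast with other markers cannot decide on this explanation. The mean log2 change of 14 endothelial loci (0.84, SD 0.34) exceeded that of 33 loci of 4 other cell types (0.10, SD 0.54) by 0.74 (permutation over genes, two-sided, p = 4.0e-05). These 4 means were 0.46 for fibroblast and preadipocyte, 0.01 for macrophage and lymphocyte, -0.03 for skeletal muscle and -0.18 for Schwann cell and nerve genes, and the first list was called without scaling (adjusted p = 0.00339). Scaling is argued against by the unscaled median of 0.40. A larger share of endothelial nuclei in cold tissue remains open, since the H3K27ac medians of the same list were 0.28 in WT, -0.08 in Txnip WT and -0.30 in Txnip KO, and no label ties the PPARG and H3K27ac libraries to the same mice.

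H3K27ac at immune loci was higher in cold in the libraries labelled Txnip KO, a list not called without scaling (adjusted p = 0.264) or with an estimated correlation (0.851). With lists of equal length the median was 0.50 (adjusted p = 0.013), which argues against longer lists in cold as the whole cause. Cells of another type in 1 of the 2 cold libraries remain a candidate explanation: the median over 14 immune loci was 0.72 in cold replicate 1 and 0.22 in cold replicate 2, against the mean of the RT libraries. The standard errors of the mean over these loci, 0.246 and 0.107, measure spread between genes and not between libraries. The median of 0.22 is too close to 0.2, the bound set for it, to decide. The biological explanation by genotype was not separated from this.

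Of 5688 strong PPARA sites of RT, 799 were missing from all cold lists. PPARG was lost too at 71 of these, more than under any permutation within bins of RT strength (highest 36, one-sided p = 1.0e-04, the smallest the permutations can give), and at 2 of the 2963 sites kept in all 3 cold libraries. With joint bins of PPARA and PPARG strength, added after the result was seen, the highest was 40. These permutations take sites and not libraries as units, and PPARG lists also covered less in cold (27.5 against 34.8 Mb). They argue against lower yield or depth as the whole cause of this overlap only as far as the bins capture site strength. With the sites of PPARG loss set aside, which leaves 728 missing, the share missing was 2.65% among the strongest and 26.4% among the weakest of bins of 569 sites, so for these 728 lower ChIP yield or depth in cold remains a candidate explanation. No biological explanation was tested.

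Splits of 3 against 3 libraries are 10, too few for a share under 0.05, and in each case 1 of the 10, the real one, gave a count as large. The real count and the highest other were 1434 and 0 for PPARG loci, 1811 and 3 for H3K27ac loci of the WT cohort, 4181 and 462 for PPARG sites gained and lost, and 2402 and 559 for H3K27ac regions gained and lost. Over the 3 cohorts together, the real split called 0 regions by exact permutation (1125 at an unadjusted p under 0.05), and its smallest possible p could not pass adjustment, so that all 100 drawn splits gave a count as large by design and say nothing about chance.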

How the results depend on the processing

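The gene body alone, the crossed pairing and the comparison of gained with lost sites were chosen after the data were seen. Where a result changed, the cause was not tested unless stated. Settings that leave 1 library in a group assume that it varies like the other groups.

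Without scaling the count of called loci was 6859 for PPARA, 1013 for H3K27ac in WT, 4424 in Txnip KO, 220 for KO against WT in cold and 16 for the interaction. Lists called were then 5 for PPARG (endothelial, fibroblast, de novo lipogenesis, lipolysis and lipid droplet, and adipocyte identity), 0 for PPARA, 3 for Txnip KO and 0 for the interaction, and the test of adipocyte identity for PPARA, relative to other loci, turned from up to down (median -1.33, adjusted p = 0.937). The PPARA changes of Ucp1, Ppargc1a, Etfdh, Arntl and Elovl6 turned to -0.28, -0.64, -0.19, -0.45 and -0.42, and only that of Ppargc1a was called (adjusted p = 0.0304).

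With stricter peaks, 1990 loci were called for PPARA, 986 in WT, 653 in Txnip WT, 1192 in Txnip KO, 54 for KO against WT at RT, 196 in cold and 35 for the interaction. PPARA sites gained and lost were 4111 and H3K27ac regions 1128, and the peak ratio of Txnip WT was 1.02. PGC1A sharing was 80.5% with PPARG, 45.5% with PPARA, 98.4% with ERR1, 60.1% with CEBPB, 54.4% with CEBPA and 85.9% with H3K27ac. Sharing was 97.9% for PPARA with PPARG, 49.9% for ERR1 with PPARG, 60.5% for CEBPA with PPARG, 86.9% for CEBPA with CEBPB and 96.2% for ERR1 at RT with cold.

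With equal lists, 379 loci were called for PPARA, 1380 in Txnip KO, 129 for KO against WT in cold and 10 for the interaction, PPARA sites were 1518 (500 gained and 1018 lost, against 83 and 8081), PPARG sites were 1850 gained and 2364 lost, and PGC1A sharing was 43.0% with PPARG, 86.8% with ERR1, 29.5% with CEBPB, 31.9% with CEBPA and 46.8% with H3K27ac. ERR1 sharing of RT with cold was 72.4%, lower because the longer list was shortened. Requiring at least 50% overlap gave 98.4% for ERR1, 63.5% for CEBPB, 67.1% for CEBPA and 88.8% for H3K27ac with PGC1A, 51.4% for ERR1 with PPARG and 70.1% for CEBPA with PPARG. Consensus in all libraries gave 84.9% for PPARG, 44.1% for PPARA, 58.2% for CEBPA and 90.4% for H3K27ac with PGC1A, 46.1% for ERR1 with PPARG, 67.8% for CEBPA with PPARG and 87.6% for CEBPA with CEBPB.

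Fitting only the groups compared called 678 loci in Txnip WT, 0 in Txnip KO (3633 unadjusted, limma), 0 for KO against WT at RT (1167), 0 in cold (1757) and 0 for the interaction (1239). Another pseudocount gave 22 and no filter 20 for KO against WT at RT. The gene body alone gave 28 at RT and 162 in cold, and turned Sox18 for PPARG to -0.0414 and Ucp1 for PPARA to -0.39. An estimated correlation called 1 list for PPARG and 0 of 22 for each of the other 7 comparisons, and over 34 list results 1 kept its call and 33 did not.

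Group means were subtracted at each locus, and the remainders of cold and RT libraries with the same replicate number were correlated. These correlations were -0.03, 0.06 and -0.06 for PPARG, 0.106, 0.0911 and 0.0679 for H3K27ac in WT, -0.201 in Txnip KO and -0.139 in Txnip WT. With 2 libraries per group the remainders mirror each other, so crossed pairs gave 0.201 in Txnip KO and 0.139 in Txnip WT. A replicate block gave 937 loci for PPARG, 1274 for Txnip KO, 0 for KO against WT at RT (1116 unadjusted, limma), 0 in cold (1779) and 0 for the interaction (1286). Crossed pairing gave 1034 in Txnip WT, 2228 in Txnip KO, 1 at RT, 46 in cold and 0 for the interaction (1667 unadjusted). With a block, 32 of the 34 list results kept their call, and the exceptions were de novo lipogenesis for PPARA (adjusted p = 0.0597) and macrophage and lymphocyte genes for KO against WT at RT (0.0642). It also ended the H3K27ac calls of Ppargc1a (0.0648) and Fasn (0.0563) in WT and the PPARG call of Acly (0.0785).

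Leaving out each library in turn gave 529 to 866 loci for PPARG, 15 to 4653 for PPARA, 851 to 2066 in WT, 292 to 528 in Txnip WT, 524 to 1937 in Txnip KO, 3 to 15 at RT, 1 to 504 in cold and 0 to 131 for the interaction (limma, 1411 unadjusted with all libraries). Sites gained and lost were 5249 to 6739 for PPARG and 8770 to 15485 for PPARA, and regions 3321 to 4625 for H3K27ac, higher in each case because fewer libraries must share a site. The libraries behind each move of a total over 1.5 times are named in the report. Gained sites alone also moved: for PPARG from 1044 to 1848 without cold 1 and 1575 without RT 2. For PPARA they moved from 83 to 172 without cold 2, 190 without cold 3, 167 without RT 1 and 125 without RT 2. Gained H3K27ac regions moved from 769 to 1691 without cold 1, 1524 without cold 2 and 1310 without RT 3. Regions over 3 cohorts gave 0 to 0 called (exact permutation, 1125 unadjusted with all libraries), a test that could not pass its threshold and says nothing about stability. PGC1A sharing stayed within 90.3 to 91.0% for PPARG, 58.4 to 60.1% for PPARA, 98.6 to 98.9% for ERR1, 65.8 to 66.6% for CEBPB, 68.7 to 69.2% for CEBPA and 92.7 to 93.0% for H3K27ac.

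Of 91 named gene results, 80 kept direction and call without scaling, 89 with another pseudocount and 91 without a filter. With stricter peaks it was 75 of 85, with equal lists 80 of 88, in the gene body alone 72 of 80, with a replicate block 77 of 91 and with only the groups compared 36 of 61. Named genes were preferred when their calls held under these alternatives, so these shares do not measure the stability of other loci. With equal lists all 9 PPARA list calls were lost, as were those of white adipocyte genes in WT (adjusted p = 0.107), lipolysis and lipid droplet genes in Txnip KO (0.0739), TCA cycle genes for KO against WT in cold (0.0939) and cAMP and immediate early genes for the interaction (0.12). A promoter window and the motif search need strand and sequence and were not run. Read depth is unknown from peak lists, so how far it limits the counts was not measured.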

Other observations

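Gene lists were set against PGC1A and PPARA sites in cold, a comparison chosen after the data were seen. A PGC1A consensus site lay at 28 of 28 oxidative phosphorylation loci, against a mean of 2.95 for random loci of matched length (random draws, two-sided, adjusted p = 0.00049), at 18 of 24 fatty acid oxidation loci (2.79 matched), 12 of 17 TCA cycle loci (2.01) and 15 of 26 thermogenesis loci (2.91), each with the same adjusted p. Endothelial, fibroblast and preadipocyte, and white adipocyte lists had 0 of 15, 0 of 14 and 0 of 11, and macrophage and lymphocyte genes had 1 of 16, at Spi1, a myeloid transcription factor gene. A PPARA site lay at 24 of 24 fatty acid oxidation loci (5.27 matched), 19 of 19 circadian clock loci (4.43) and 13 of 28 oxidative phosphorylation loci, against 20.3% of all loci.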
